A study of Mus musculus with 9 samples.

How the data were processed

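RNA from mouse liver was hybridized to Illumina bead arrays, 3 arrays in each of 3 groups: euthyroid, T3 for 3 days, and T3 with FoxO1 siRNA. The groups and replicate numbers were taken from the sample titles. Per the labels, RNA was extracted with Trizol and RNeasy and labelled with biotin by in vitro transcription. The authors deposited one file of probe signal intensities before normalization and, per the file headers, a detection p-value for each probe and array. The signals are linear and are not background-subtracted, and the p-values rise in steps that imply 936 negative controls. A second set of values, deposited by the authors for the same arrays, holds quantile-normalized intensities on a linear scale: its sorted values differ from the mean sorted signals by at most 0.0693%, and each of its 9 columns correlates best with the signals of its own array. The submitters name Partek 6.6 without saying which step it did. The scanner settings are not given in the sources used here.

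The signals were read in R 4.3.3 and processed with limma 3.58.1 and statmod 1.5.0. The neqc function corrected the background from negative controls inferred from the detection p-values, added an offset of 16, normalized by quantiles and took log2. Probes with a detection p-value under 0.05 on at least 3 of the 9 arrays were kept, 18581 of 45281. Of all probes, 34885 map to 1 gene symbol, 18 to several and 10378 to none; those with several or none were left out of the gene tests, and the 2827 unnamed probes that passed the filter were tested apart. For each symbol the probe with the highest mean log2 value was used, which gave 10408 genes from 15754 probes. Of the 3765 genes with several tested probes, 32, 8 and 36 had probes called in opposite directions in the 3 comparisons. Agreement in sign alone was lower. Of 766, 747 and 1117 called genes with several probes, 579, 630 and 850 had all other probes in the same direction.

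One linear model with 3 group means was fitted to all 9 arrays (lmFit and eBayes), and the 3 differences between groups were tested, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The tests, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The named genes are Foxo1, the 6 largest rises and 6 largest falls of the first and second comparison and 3 of each of the third, among genes past the threshold whose 3 arrays of one group all lie above the 3 of the other. They include up to 6 genes moved back in each direction, up to 4 members of each list with the lowest adjusted p, and Thrsp, Dio1, Me1, Klf9, G6pc and Pck1. Predicted genes were passed over. The members of small counts named without a value were chosen after their values were seen, as were Fmo2, Hr, Fgb, Dcn and Abcg5.

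The 30 lists cover thyroid hormone targets, thyroid hormone and FoxO machinery, FoxO targets, gluconeogenesis, lipogenesis, cholesterol synthesis, bile acid and sterol transport, fatty acid oxidation and ketogenesis, oxidative phosphorylation, autophagy and lysosome, the circadian clock, the acute phase response, the interferon response, the cell cycle, male-biased and female-biased liver genes, xenobiotic metabolism, amino acid catabolism and urea cycle, the unfolded protein and integrated stress response and immediate early genes. The others hold markers of hepatocytes, macrophages, neutrophils and monocytes, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, lymphocytes, erythroid cells, adipocytes and exocrine pancreas. Some genes stand in several lists (Pck1 and Pdk4, for example). Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over 90 tests. Of these, 39 passed; with an estimated correlation 0 passed, with adjusted p-values of 0.251 or more (17 had an unadjusted p under 0.05). The fry test, which asks whether a list's genes move on balance in one direction without comparing them with other genes, passed for 48.

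Opposite changes were counted as genes past the threshold in both the first and the second comparison with opposite signs. Since both use the T3 arrays, 1000 data sets without group effects were simulated from each gene's residual spread for the covariance and correlation. In a fit added after the results were seen, the 3 T3 arrays were divided between the comparisons, 1 and 2, with 4 group means; the lone array is assumed to vary like the other groups. The fit and the threshold were tested on simulated data in which 200 of 10408 genes were changed. In these data 4-fold changes were recovered in 93.9% to 97.0% of cases, 2-fold changes in 73.1% to 83.6% and 1.5-fold changes in 38.8% to 46.3%. Of the calls 2.68% to 7.28% were false. Noise independent between genes was added to normalized values, so the background, normalization, filter and probe steps were not tested. Each comparison had 1 draw, with 66 or 67 genes per fold. Alternatives changed the background step, the normalization, the filter, the probe per gene, the model, the threshold and the arrays used, one at a time. The labels and files give no slide for the arrays, so no slide term was fitted.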

Results

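The data are 9 Illumina bead arrays of liver RNA from male C57BL/6 mice aged 8 weeks, with 3 arrays in each of 3 groups. The first group was euthyroid. The second had received the thyroid hormone triiodothyronine (T3) for 3 days, which per the labels made the mice hyperthyroid. The third had received T3 and a small interfering RNA (siRNA) against FoxO1, a forkhead transcription factor that insulin signalling keeps out of the nucleus. The siRNA was given into the tail vein by hydrodynamic injection, a rapid injection of a large volume that brings nucleic acid into hepatocytes. The median probe signal was between 109 and 127 on each array, and between 16481 and 18357 of the 45281 probes (36.4% to 40.5%) were detected. After the filter 10408 genes were tested, and the number of arrays, 3 per group, limits the precision of each value. The labels do not say whether each array is a separate mouse, so the p-values measure the spread between these samples. All changes below are log2 fold changes with the SE of the limma fit and n = 3 arrays per group, and adjusted p-values are over all 10408 genes unless a list is named.

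Foxo1 (Entrez Gene 56458, GRCm38 chromosome 3, 52268337 to 52350109), the gene that the siRNA targets, had 2 probes, both detected on all 9 arrays. On the brighter probe the normalised log2 signal was 8.76 ± 0.08 (SD, n = 3) in euthyroid liver, 9.53 ± 0.29 (SD, n = 3) with T3 and 8.46 ± 0.06 (SD, n = 3) with T3 and the siRNA. Foxo1 was thus 2.10-fold lower with the siRNA than with T3 alone (log2 change -1.07 ± 0.14, adjusted p = 0.00166), and every siRNA array lay under every T3 array. It was 1.71-fold higher with T3 than in euthyroid liver (0.77 ± 0.14, adjusted p = 0.00805), a call that was lost with median scaling. The dimmer probe read 6.85 ± 0.09 (SD, n = 3), 6.90 ± 0.19 (SD, n = 3) and 6.15 ± 0.25 (SD, n = 3) in the same order. On that probe Foxo1 also fell with the siRNA relative to T3 (log2 change -0.74, adjusted p = 0.0131 over the probes), but the T3 and euthyroid groups differed by only 0.05 (adjusted p = 0.851). Against euthyroid liver the siRNA group gave -0.30 ± 0.14 on the brighter probe (adjusted p = 0.15) and -0.69 ± 0.15 on the dimmer one (adjusted p = 0.0117).

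**Figure D1:**
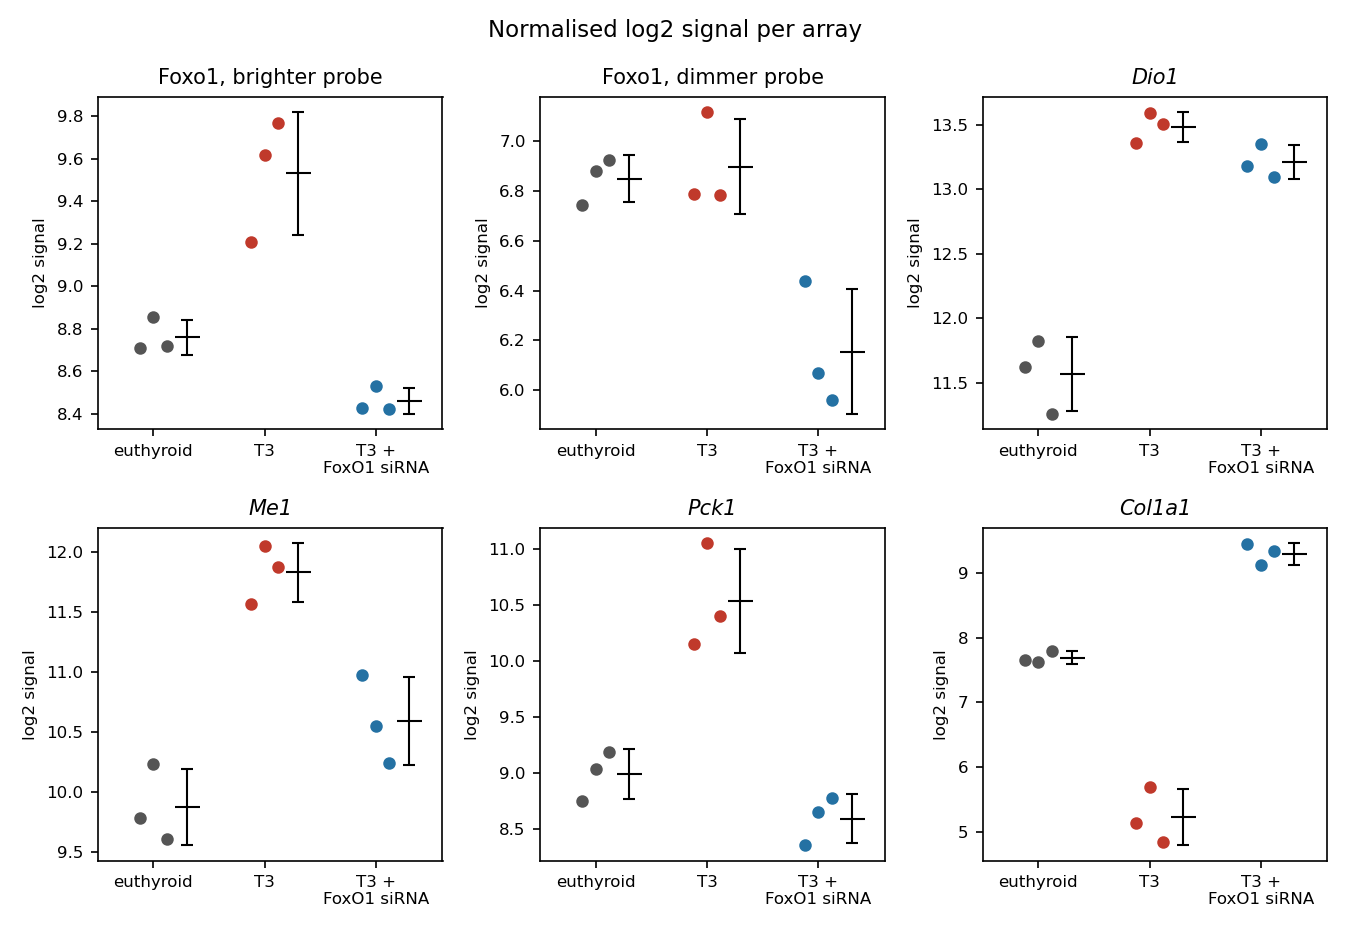
Normalised log2 signal of both Foxo1 probes and of Dio1, Me1, Pck1 and Col1a1 on each of the 9 arrays (points), with the mean and SD of the 3 arrays of a group (bars). On both Foxo1 probes the 3 siRNA arrays lie under the 3 T3 arrays; Dio1 stays high with the siRNA, Me1 lies between the other two groups, and Col1a1 is lowest with T3 alone.

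The comparison of T3 with euthyroid liver asks which hepatic transcripts differ after 3 days of thyroid hormone. Dio1, the deiodinase that converts thyroxine to T3 and a standard marker of thyroid hormone action in liver, was 3.78-fold higher with T3 (1.92 ± 0.15, adjusted p = 0.000595), and its other probe rose as well (2.48). Me1, the malic enzyme that supplies NADPH for fatty acid synthesis, was 3.87-fold higher (1.95 ± 0.22, adjusted p = 0.00152), and Pck1, the phosphoenolpyruvate carboxykinase of gluconeogenesis, 2.91-fold higher (1.54 ± 0.23, adjusted p = 0.00366). The largest rise was that of the steroid hydroxylase Cyp17a1, 28.0-fold (4.81 ± 0.46, adjusted p = 0.000874), followed by A1bg at 15.4-fold (3.94 ± 0.74, adjusted p = 0.00883; 1.77 on its other probe) and the hydroxysteroid dehydrogenase Akr1c18 at 10.3-fold (3.36 ± 0.62, adjusted p = 0.00803). Serpina7, which encodes thyroxine-binding globulin, was 7.85-fold lower (-2.97 ± 0.29, adjusted p = 0.000897; -1.62 on its other probe), and Col1a1, a chain of type I collagen, 5.48-fold lower (-2.45 ± 0.20, adjusted p = 0.000595). The signals were dim in part: Col1a1 was detected on 1 of the 3 T3 arrays, and in euthyroid liver A1bg was detected on 1 array and Akr1c18 on 2.

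Of the 10408 genes 1919 passed the threshold, 813 higher and 1106 lower with T3, and 1072 of them changed at least 1.5-fold. The other largest rises were those of Wfdc16 (2.88 ± 0.28, at least 4.45-fold since it was not detected on the euthyroid arrays), Cyp2b23 (2.78 ± 0.60) and the lens crystallin Crybb3 (2.75 ± 0.34). Cyp2b23 was detected on 2 of the 3 euthyroid arrays, and Hectd2os on 1 of the 3 T3 arrays. The other largest falls were those of the noncoding transcript Hectd2os (-3.13 ± 0.17), the male-typical fatty acid hydroxylase Cyp4a12b (-2.40 ± 0.39), Lpgat1 (-2.16 ± 0.19, although a second probe of this gene gave 0.76) and the pseudogene Pisd-ps3 (-2.14 ± 0.29; -0.49 on its other probe). Of the other thyroid hormone responders fixed in advance, Thrsp (0.63 ± 0.21, adjusted p = 0.0642), Klf9 (0.15 ± 0.21, adjusted p = 0.655) and G6pc (-0.36 ± 0.29, adjusted p = 0.417) did not pass, and the 2 probes of Thrsp differed in sign (0.63 and -0.62). The groups did not overlap for 40.7% of the genes, where chance gives 10%. The count of 1919 fell to 906 without euthyroid replicate 1, 1190 without euthyroid replicate 2, 1146 without euthyroid replicate 3 and 1221 without T3 replicate 3, and it was 916 with median scaling. Some named transcripts belong to sets of close copies (Cyp2b9 and Cyp2b23, Cyp4a12a and Cyp4a12b, Gsta1 and Gsta2, Saa1 and Saa2) whose probes were not checked for cross-hybridization, and the offset of the background step makes the folds of dim probes too small.

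Cholesterol synthesis was the metabolic list with the most members changed by T3: of 16 measured genes 12 rose and none fell (12 rose and 1 fell adjusted over the list alone). Cyp51, the lanosterol demethylase, rose by 1.66 ± 0.15, the squalene epoxidase Sqle by 1.53 ± 0.15 and the sterol oxidase Msmo1 by 1.08 ± 0.15. The list's median was 0.93 (camera adjusted p = 6.48e-09; adjusted p = 0.251 with an estimated correlation). Of 20 thyroid hormone targets 5 rose (8 adjusted over the list alone), namely Dio1, Me1, Pck1, the sterol transporter Abcg5 and Pdk4, the kinase that turns off pyruvate dehydrogenase (1.36 ± 0.19). Their median was 0.39 (camera adjusted p = 0.000106; adjusted p = 0.251 with an estimated correlation). In lipogenesis 4 of 17 genes rose (7 rose and 1 fell adjusted over the list alone), namely Me1, the lipase Pnpla3 (1.90 ± 0.35), Gpam and Acss2. Only 2 rose without euthyroid replicate 2, euthyroid replicate 3 or T3 replicate 3. The median was 0.35 (camera adjusted p = 0.00262; adjusted p = 0.31 with an estimated correlation). In oxidative phosphorylation 7 of 17 rose (10 adjusted over the list alone), among them Cycs, cytochrome c (0.53 ± 0.10), and Cox5a (0.43 ± 0.09), both no longer called with median scaling. The count of 7 was 3 without euthyroid replicate 2 or euthyroid replicate 3. The median of that list was 0.32 (camera adjusted p = 5.78e-05; adjusted p = 0.264 with an estimated correlation).

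In bile acid and sterol transport 7 of 18 genes rose and 1 fell, the same counts as adjusted over the list alone. The basolateral bile acid exporter subunit Slc51b rose by 2.71 ± 0.31 (detected on 1 of 3 euthyroid arrays), the canalicular bile salt pump Abcb11 by 0.84 ± 0.11 and the phospholipid transporter Abcb4 by 0.76 ± 0.11, while the basolateral exporter Abcc3 changed by -1.90 ± 0.14. The list's median was 0.19 (camera adjusted p = 0.0404; adjusted p = 0.366 with an estimated correlation), and the call was lost without euthyroid replicate 2 (0.0554), without siRNA replicate 1 (0.0567) and with a filter for detection on all 9 arrays (0.0771). Of 24 FoxO targets 6 rose (6 adjusted over the list alone), including Pdk4, Pck1, the lipid transfer protein Mttp (0.78 ± 0.13) and the cyclin Ccng2 (1.08 ± 0.19). Their median was 0.24, and 0.15 without T3 replicate 1 (camera adjusted p = 0.00327; adjusted p = 0.251 with an estimated correlation). Of 12 genes of the thyroid hormone and FoxO machinery 3 rose (3 adjusted over the list alone), namely Foxo1, Dio1 and Sirt1, the last lost in 10 alternatives. The median was 0.23 (camera adjusted p = 0.0146; adjusted p = 0.259 with an estimated correlation), lost with the mean of a gene's probes (0.225; median 0.11); without a filter the median was 0.14. In fatty acid oxidation and ketogenesis 3 of 17 rose (3 adjusted over the list alone), Pdk4, Hadh and Etfdh. The other probe of Hadh gave 0.02 (against 1.01), and the 3 other probes of Etfdh -0.12 to 1.04 (against 0.61). The median was 0.14 (camera adjusted p = 0.0297; adjusted p = 0.31 with an estimated correlation). That call was lost without euthyroid replicate 3 (0.0613) and with detection on all 9 arrays (0.0771), where the median was 0.07; it was 0.36 with the mean of a gene's probes and 0.22 without T3 replicate 1.

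Among the listed genes that are higher in female than in male liver, most of those measured rose in these male mice. The list holds 17 genes, of which 15 are on the array and 10 passed the filter. A gene could pass that filter by detection in 1 group alone. Of 10 female-biased genes 7 were higher with T3 and 1, Fmo2, was lower (8 and 1 adjusted over the list alone). Among the rises were Cyp17a1, A1bg, the cytochrome P450 gene Cyp2a4 (2.33 ± 0.27) and the repressor Cux2 (1.97 ± 0.37, and 0.79 on its other probe, detected on 1 of 3 euthyroid arrays). Without T3 replicate 2 only 4 were higher, and without euthyroid replicate 1 Fmo2 was not called. The median was 1.96, and 1.22 with the authors' values (camera adjusted p = 0.000208; adjusted p = 0.251 with an estimated correlation). Of 14 male-biased genes 6 fell and 1 rose (7 and 1 adjusted over the list alone). Cyp4a12b, the complement component C6 (-1.97 ± 0.32) and Susd4 (-1.55 ± 0.28) fell, while the major urinary protein Mup20 rose by 1.31 ± 0.13. The median was -0.67 (camera adjusted p = 0.025; adjusted p = 0.515 with an estimated correlation), and the call was lost without T3 replicate 2 (0.143) and with array weights (0.0501).

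Of 11 markers of stellate cells and fibroblasts 6 were lower with T3 (7 adjusted over the list alone), among them Col1a1, the smooth muscle actin Acta2 (-2.07 ± 0.32; -1.70 to -0.36 on its 3 other probes) and Col3a1 (-1.27 ± 0.18). Without euthyroid replicate 1 or euthyroid replicate 3 the count was 3. Their median was -0.51 (camera adjusted p = 0.00212; adjusted p = 0.251 with an estimated correlation). Of 10 macrophage markers 1 passed, Lyz2 (0.69 ± 0.18, a call lost in 7 of the alternatives), with a list median of 0.27 (camera adjusted p = 0.011; adjusted p = 0.264 with an estimated correlation; 1 higher adjusted over the list alone). In the interferon response 3 of 19 rose (3 adjusted over the list alone), the viral RNA sensor Ifih1 (1.53 ± 0.25, at least 2.17-fold), the guanylate-binding protein Gbp3 (1.38 ± 0.27) and Psmb8. The 2 probes of Psmb8 differed in sign (0.76 and -0.57), and its call was lost in 8 alternatives. The median was 0.38 (camera adjusted p = 0.00107; adjusted p = 0.31 with an estimated correlation). T3 replicate 2 stood apart, with a list median above the euthyroid mean of 0.67 against 0.17 and 0.15 on T3 replicates 1 and 3. The median was 0.25 without it and 0.24 with the authors' values. Of 17 genes of the unfolded protein and integrated stress response 4 rose (4 adjusted over the list alone), among them the chaperones Hspa5 (0.86 ± 0.14) and Calr (0.96 ± 0.17). Without euthyroid replicate 1 only 2 rose. Their median was 0.24 (camera adjusted p = 0.0199; adjusted p = 0.259 with an estimated correlation), lost without T3 replicate 2 (0.0507); the median was 0.16 with the authors' values. The 11 hepatocyte markers had 1 rise, Cps1, and 1 fall, Hpd (1 and 1 adjusted over the list alone); the rise was not called without euthyroid replicate 2 or euthyroid replicate 3. The median was -0.02 (camera adjusted p = 0.839). The 1 measured exocrine pancreas marker, the elastase Cela2a, rose by 1.65 ± 0.22 (camera adjusted p = 0.0478; adjusted p = 0.259 with an estimated correlation; 1 higher adjusted over the list alone). The list call was lost in 10 alternatives, 6 of which left out 1 array, and the median was 0.07 without a filter on dim probes, where more of these markers are tested.

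**Figure D2:**
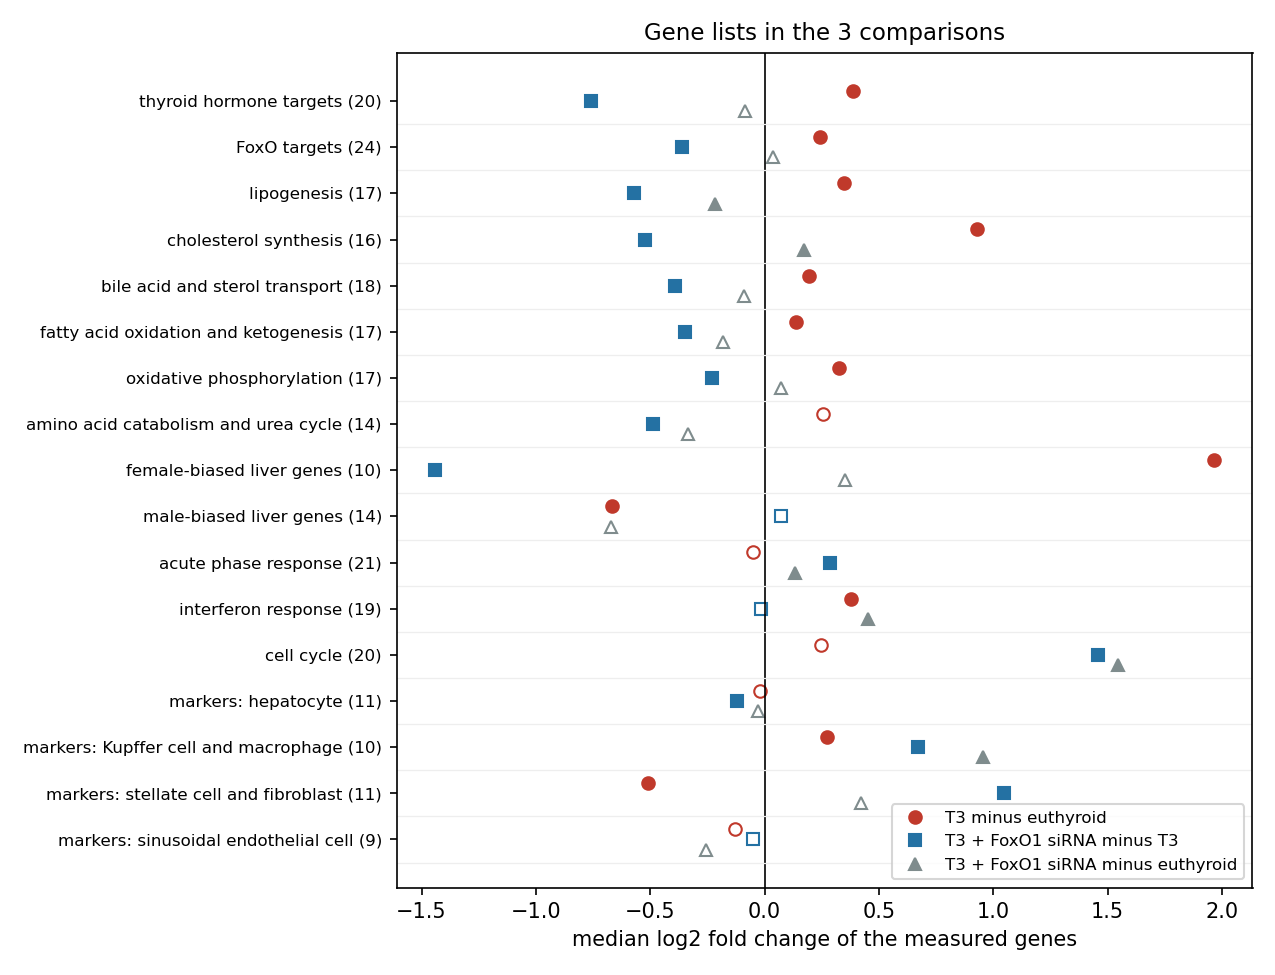
Median log2 fold change of the measured genes of 17 gene lists in the 3 comparisons (number of measured genes in brackets). Filled symbols passed camera with the preset correlation at an adjusted p under 0.05, and no list passed with an estimated correlation; cholesterol synthesis has a median of 0.93 with T3 and -0.52 when the siRNA was added, and the cell cycle list has 1.46 when the siRNA was added.

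The comparison of T3 plus FoxO1 siRNA with T3 alone asks which transcripts differ when the siRNA is added to thyroid hormone. The largest rises included a matrix gene, an actin of contractile cells and an acute phase gene. Col1a1, detected on 1 of the 3 T3 arrays, was 16.6-fold higher with the siRNA (4.06 ± 0.20, adjusted p = 1.67e-05), Acta2, the actin of activated stellate cells, 21.5-fold (4.42 ± 0.32, adjusted p = 0.000135; 2.13 to 3.55 on its 3 other probes) and Lcn2, the acute phase protein lipocalin 2, 31.1-fold (4.96 ± 0.58, adjusted p = 0.000881). Gpnmb, a glycoprotein of lipid-laden macrophages, was at least 25.4-fold higher and was not detected on the T3 arrays (5.37 ± 0.46, adjusted p = 0.000265). Genes of lipid and glucose metabolism were lower: Pck1 by -1.94 ± 0.23 (adjusted p = 0.000885), the phosphatidate phosphatase Lpin1 by -2.45 ± 0.32 (adjusted p = 0.00158), the fatty acid synthase Fasn by -1.38 ± 0.18 (adjusted p = 0.00143) and Me1 by -1.24 ± 0.22 (adjusted p = 0.00623). Dio1 did not pass (-0.28 ± 0.15, adjusted p = 0.229).

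Of the 10408 genes 2035 passed, 1226 higher and 809 lower with the siRNA, and 1281 changed at least 1.5-fold. Among the largest changes were also rises of the serum amyloid Saa2 (3.58 ± 0.56) and of the macrophage elastase Mmp12 (3.31 ± 0.52, at least 6.6-fold). Mfsd2a, a transporter of lysophosphatidylcholine (-3.00 ± 0.54), the acyl-CoA thioesterase Acot3 (-2.59 ± 0.44), the hepcidin gene Hamp2 (-2.28 ± 0.24), Unc79 (-2.17 ± 0.33) and the collectin Colec10 (-2.09 ± 0.22) fell. Klf9 (-0.77 ± 0.21, adjusted p = 0.0314) and Thrsp (-0.75 ± 0.21, adjusted p = 0.0341) passed, but Klf9 was no longer called in 4 alternatives and Thrsp in 7, with adjusted p-values up to 0.088 and 0.0914. G6pc did not pass (-0.76 ± 0.29, adjusted p = 0.0945). The groups did not overlap for 38.4% of the genes, where chance gives 10%. The count of 2035 was 1148 without siRNA replicate 3 and 1345 without T3 replicate 3, and with median scaling 88.7% of the genes past the threshold were higher in place of 60.2%. The labels name no group injected without FoxO1 siRNA and do not say whether the other mice had a control injection, so this comparison cannot be read as the fall of Foxo1 without the injection.

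In lipogenesis 12 of 17 genes were lower with the siRNA and none higher (14 lower adjusted over the list alone); without T3 replicate 3 only 5 were lower. Acss2, which makes acetyl-CoA from acetate, changed by -1.60 ± 0.21, beside Fasn and Me1. The median was -0.57 (camera adjusted p = 1.49e-06; adjusted p = 0.251 with an estimated correlation). In cholesterol synthesis 9 of 16 fell (10 adjusted over the list alone), including the isomerase Idi1 (-1.24 ± 0.20), the mevalonate pathway kinase Pmvk (-0.96 ± 0.17) and the final reductase Dhcr7 (-0.95 ± 0.17). The median was -0.52 (camera adjusted p = 0.000103; adjusted p = 0.354 with an estimated correlation). Of 20 thyroid hormone targets 10 fell and 1, Hr, rose (12 and 2 adjusted over the list alone). The coactivator Ppargc1b (-1.35 ± 0.14), the sterol transporter Abcg8 (-1.29 ± 0.25), Pck1, Me1 and Fasn were among the falls. The count of 10 was 6 without T3 replicate 3, and Hr was not called without siRNA replicate 3. The median was -0.76 (camera adjusted p = 5.78e-05; adjusted p = 0.251 with an estimated correlation). Of 24 FoxO targets 5 fell (5 adjusted over the list alone), Pck1, Ccng2, Pdk4, Ppargc1a and the insulin-repressed secreted protein Igfbp1 (-1.92 ± 0.47; detected on 2 of 3 siRNA arrays), of which all but Pck1 lost their call in at least 1 alternative. The count of 5 was 3 without T3 replicate 3, siRNA replicate 2 or siRNA replicate 3. The median was -0.36 (camera adjusted p = 0.00203; adjusted p = 0.251 with an estimated correlation). In the thyroid hormone and FoxO machinery 2 of 12 fell (2 adjusted over the list alone), Foxo1 and Rxra, and only 1 when any 1 of 6 arrays was left out. The median was -0.34, and -0.14 with median scaling (camera adjusted p = 0.00362; adjusted p = 0.251 with an estimated correlation).

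In fatty acid oxidation and ketogenesis 6 of 17 genes fell (6 adjusted over the list alone), including the fatty acid hydroxylase Cyp4a14 (-1.56 ± 0.17), the thioesterase Acot1 (-1.54 ± 0.22) and the nuclear receptor Ppara (-0.92 ± 0.22, lost with median scaling and without T3 replicate 1). Without siRNA replicate 2 only 3 fell. The median was -0.35, and -0.22 without siRNA replicate 3 (camera adjusted p = 0.000661; adjusted p = 0.251 with an estimated correlation). In bile acid and sterol transport 9 of 18 fell and 1 rose (9 and 1 adjusted over the list alone), with the sterol hydroxylase Cyp27a1 at -0.88 ± 0.11 and Abcc3 higher by 0.83 ± 0.14. Without siRNA replicate 3 only 3 fell. The median was -0.39 (camera adjusted p = 0.00535; adjusted p = 0.259 with an estimated correlation). In amino acid catabolism and the urea cycle 8 of 14 fell (8 adjusted over the list alone), among them the proline dehydrogenase Prodh (-0.93 ± 0.14), Hpd of tyrosine breakdown (-0.80 ± 0.14) and the arginase Arg1 (-0.50 ± 0.10). The median was -0.49 (camera adjusted p = 0.0004; adjusted p = 0.264 with an estimated correlation). In gluconeogenesis 3 of 11 fell (4 adjusted over the list alone), Pck1, Pcx and Ppargc1a. Only 1 fell without T3 replicate 2, T3 replicate 3, siRNA replicate 2 or siRNA replicate 3. Their list's median was -0.29, and -0.13 with median scaling (camera adjusted p = 0.0404; adjusted p = 0.251 with an estimated correlation), lost without T3 replicate 3 (0.0506), without siRNA replicate 1 (0.0707) and with detection on all 9 arrays (0.061). In oxidative phosphorylation 2 of 17 fell (2 adjusted over the list alone), Sdhb and Cyc1, both lost with median scaling and without T3 replicate 2, T3 replicate 3, siRNA replicate 2 or siRNA replicate 3. The median was -0.23 (camera adjusted p = 0.00262; adjusted p = 0.381 with an estimated correlation). Of 10 female-biased genes 7 fell (8 adjusted over the list alone), including Acot3, Cyp4a14 and Cyp2a4 (-1.27 ± 0.27). The count of 7 was 3 without T3 replicate 2 or siRNA replicate 1. The median was -1.44 (camera adjusted p = 0.00107; adjusted p = 0.259 with an estimated correlation). Of 14 male-biased genes 2 fell (1 adjusted over the list alone), the elongase Elovl3 (-1.56 ± 0.28) and Mup20, and only 1 when any 1 of 8 arrays was left out. The median was 0.07 (camera adjusted p = 0.874).

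Cell cycle genes rose with the siRNA: 15 of 20 were higher and none lower (20 higher adjusted over the list alone). The mitotic kinase Cdk1 rose by 2.03 ± 0.25, Aurka by 1.65 ± 0.21, the spindle checkpoint kinase Bub1b by 1.37 ± 0.19 and the survivin gene Birc5 by 2.57 ± 0.38. The median was 1.46 (camera adjusted p = 9.29e-10; adjusted p = 0.264 with an estimated correlation). In the acute phase response 9 of 21 rose and 1, the fibrinogen chain Fgb, fell (9 and 1 adjusted over the list alone); the fall was not called when any 1 of 4 arrays was left out. Beside Lcn2 and Saa2, Saa1 rose by 3.06 ± 0.37 and the orosomucoid Orm2 by 1.62 ± 0.13. The median was 0.29 (camera adjusted p = 0.00535; adjusted p = 0.251 with an estimated correlation), lost with median scaling (0.0877); the median was 0.16 without a filter and 0.18 without siRNA replicate 2.

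Of 10 macrophage markers 6 rose (6 adjusted over the list alone), including the complement components C1qa (0.87 ± 0.15) and C1qc (0.85 ± 0.15), the surface marker Adgre1 (0.78 ± 0.15) and Vsig4 (0.67 ± 0.11). The median was 0.67 (camera adjusted p = 0.00212; adjusted p = 0.251 with an estimated correlation). Of 11 stellate cell and fibroblast markers 7 rose and 2, Reln and Dcn, fell (7 and 2 adjusted over the list alone). Neither fall was called without T3 replicate 1, T3 replicate 3, siRNA replicate 1 or siRNA replicate 3. Col3a1 rose by 1.69 ± 0.18 and the matrix protein Sparc by 1.05 ± 0.11, beside Col1a1 and Acta2. The median was 1.05, and 0.57 with detection on all 9 arrays (camera adjusted p = 0.00107; adjusted p = 0.251 with an estimated correlation). None of the 9 sinusoidal endothelial markers passed (0 adjusted over the list alone). The median was -0.05 (camera adjusted p = 0.874). The probe of albumin, Alb, read only 9.2 to 10.2 (log2) on the T3 arrays, where the hepatocyte marker Ahsg read 15.6. Whether that probe reads the main albumin transcript was not checked. Of 11 hepatocyte markers 3 fell (3 adjusted over the list alone), Hpd, the urea cycle enzyme Ass1 (-0.50 ± 0.11) and Alb (-1.08 ± 0.25, lost with median scaling and without siRNA replicate 3). Their median was -0.12 (camera adjusted p = 0.0354; adjusted p = 0.251 with an estimated correlation), lost without siRNA replicate 1 (0.0728), with cyclic loess (0.223) and with detection on all 9 arrays (0.0557); the median was -0.19 without T3 replicate 1.

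The comparison of T3 plus FoxO1 siRNA with euthyroid liver shows where the 2 treatments together leave each transcript. Lcn2 was 24.4-fold higher than in euthyroid liver (4.61 ± 0.58, adjusted p = 0.00113), Akr1c18 19.5-fold (4.29 ± 0.62, adjusted p = 0.00198) and Gpnmb 14.4-fold (3.85 ± 0.46, adjusted p = 0.000979). Hectd2os was at least 9.63-fold lower and was not detected on the siRNA arrays (-3.74 ± 0.17, adjusted p = 1.3e-05), Cyp4a12b 8.99-fold lower (-3.17 ± 0.39, adjusted p = 0.00104) and Elovl3 6.87-fold lower (-2.78 ± 0.28, adjusted p = 0.000595). Dio1 stayed above its euthyroid level (1.64 ± 0.15, adjusted p = 0.000434), and Pck1 did not differ past the threshold (-0.40 ± 0.23, adjusted p = 0.222). Me1 was higher by 0.72 ± 0.22 (adjusted p = 0.0415, lost in 8 alternatives, up to 0.126) and G6pc lower by -1.12 ± 0.29 (adjusted p = 0.0206, lost in 4 alternatives, up to 0.069). Klf9 (-0.62 ± 0.21, adjusted p = 0.0524) and Thrsp (-0.13 ± 0.21, adjusted p = 0.69) did not pass. The dimmer probe of Thrsp, detected on 8 arrays, did fall (-2.06 ± 0.49, limma adjusted p = 0.0155 over the probes). The 2 probes thus leave open whether Thrsp differed from its euthyroid level. Of the 10408 genes 2785 passed, 1401 higher and 1384 lower, and the groups did not overlap for 46.1% of the genes, where chance gives 10%. The count was 1698 without euthyroid replicate 1, 1764 without euthyroid replicate 2, 1745 without siRNA replicate 3 and 1778 with median scaling.

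The 20 measured cell cycle genes were higher than in euthyroid liver (20 adjusted over the list alone), with Cdk1 at 2.19 ± 0.25, the topoisomerase Top2a at 2.64 ± 0.36 (0.99 on its other probe; detected on 1 of 3 euthyroid arrays) and the cyclin Ccnd1 at 1.49 ± 0.22. The median was 1.55 (camera adjusted p = 1.51e-11; adjusted p = 0.259 with an estimated correlation). Of 10 macrophage markers 8 were higher (9 adjusted over the list alone), with the complement receptor Vsig4 at 0.90 ± 0.11 and C1qc at 1.13 ± 0.15. The median was 0.96 (camera adjusted p = 3.35e-05; adjusted p = 0.251 with an estimated correlation). In the unfolded protein and integrated stress response 8 of 17 were higher (9 adjusted over the list alone), including the chaperone genes Dnajb9 (1.22 ± 0.16), Calr (1.02 ± 0.17) and Hspa5 (0.68 ± 0.14). The count of 8 was 4 without euthyroid replicate 3, siRNA replicate 2 or siRNA replicate 3. The median was 0.43 (camera adjusted p = 0.0091; adjusted p = 0.251 with an estimated correlation). In the acute phase response 8 of 21 were higher and 1 lower, a fall not called when any 1 of 4 arrays was left out (8 and 1 adjusted over the list alone), with Saa1 at 3.21 ± 0.37 and Orm2 at 1.63 ± 0.13. The median was 0.13 (camera adjusted p = 0.0189; adjusted p = 0.259 with an estimated correlation), lost with median scaling (0.101); the median ranged from 0.08 without a filter to 0.46 with the mean of a gene's probes. Of 6 neutrophil and monocyte markers 2 were higher (2 adjusted over the list alone), Lyz1 (1.23 ± 0.18) and Ly6c1 (0.84 ± 0.18, detected on 2 of 3 euthyroid arrays). Ly6c1 already read 6.384 to 6.455 (log2) with T3 alone, against 5.369 to 5.64 in euthyroid liver. The other 4 markers, among them S100a8 and S100a9, did not pass. The list's median was 0.62 (camera adjusted p = 0.0146, and adjusted p = 0.402 with an estimated correlation). The siRNA arrays differed: the list median above the euthyroid mean was 0.70, 0.07 and 1.16 on replicates 1, 2 and 3. The median was 0.93 without siRNA replicate 2, 0.34 without siRNA replicate 3, and 0.40 with array weights and with the authors' values. In the interferon response 6 of 19 were higher (7 higher and 1 lower adjusted over the list alone), including the guanylate-binding proteins Gbp3 (1.17 ± 0.27) and Gbp2. Without euthyroid replicate 2 or euthyroid replicate 3 only 3 were higher. The median was 0.45 (camera adjusted p = 0.0347; adjusted p = 0.478 with an estimated correlation), lost without euthyroid replicate 3 (0.0752) and with detection on all 9 arrays (0.0503); the median was 0.29 with the authors' values.

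Lipogenesis lay under its euthyroid level in 6 of 17 genes and above it in 1, Me1 (7 and 1 adjusted over the list alone). Fasn was lower by -0.88 ± 0.18 (lost with median scaling). Without euthyroid replicate 1 only 2 genes were lower and none higher, and without euthyroid replicate 2 or euthyroid replicate 3 the lower ones were 3. The median was -0.22 (camera adjusted p = 0.0406; adjusted p = 0.462 with an estimated correlation). That call was lost without euthyroid replicate 3 (0.0904), without siRNA replicate 1 (0.0567), without siRNA replicate 3 (0.0793), with array weights (0.0564) and with detection on all 9 arrays (0.0642). The median ranged from -0.39 with the mean of a gene's probes to -0.11 without siRNA replicate 3. Cholesterol synthesis stayed above it in 3 of 16 genes, Sqle (1.62 ± 0.15), Cyp51 (1.12 ± 0.15) and Msmo1 (0.81 ± 0.15), and lay under it in 1, Stard4, which was not called when any 1 of 4 arrays was left out (3 and 1 adjusted over the list alone). The median was 0.17, and up to 0.34 with the mean of a gene's probes (camera adjusted p = 0.0475; adjusted p = 0.586 with an estimated correlation). That call was lost in 7 alternatives, among them without euthyroid replicate 3 (0.177), without T3 replicate 2 (0.0529), without siRNA replicate 1 (0.101) and without siRNA replicate 2 (0.085). Of 20 thyroid hormone targets 3 were higher and 6 lower (5 and 7 adjusted over the list alone). Only 3 were lower without any 1 of the euthyroid arrays. The median was -0.09 (camera adjusted p = 0.808). Of 11 stellate cell and fibroblast markers 5 were higher, with Acta2 at 2.35 ± 0.32, the protease inhibitor Timp1 at 2.15 ± 0.33 (detected on 1 of 3 euthyroid arrays) and Col1a1 at 1.60 ± 0.20, and 2 were lower, Reln (-1.20 ± 0.15) and Dcn (5 and 2 adjusted over the list alone; 1 lower without euthyroid replicate 1). Their median was 0.42 (camera adjusted p = 0.0562), and the list passed in 13 alternatives.

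The fold changes of T3 against euthyroid and of the siRNA against T3 ran in opposite directions more often than in the same direction. Of the 813 genes that T3 raised, 245 (30.1%) were lower again with the siRNA and 18 rose further. Of the 1106 genes that T3 lowered, 307 (27.8%) were higher again and 41 fell further. Independent lists of these sizes would share 63.2, 95.8, 130 and 86.0 genes in the same order. The T3 arrays enter both comparisons with opposite signs, which by itself favours opposite calls and a negative covariance, so 1000 data sets were simulated without any group effect. In these sets the genes were drawn independently, and correlated genes would widen the simulated range. The covariance of the fold changes over all genes was -0.0810 against -0.0198 on average in the simulated sets (range -0.0224 to -0.0174), a difference of -0.0613. The correlation went the other way: it was -0.385 (Spearman -0.375), weaker than the average of -0.5002 in the simulated sets (range -0.538 to -0.453). The design sets it near that average without effects, and changes found in only one of the comparisons move it towards 0. To take the shared arrays out, 1 T3 array was used in one comparison and the other 2 in the other, in each of the 6 ways. This was chosen after the results were seen. The covariance was then -0.0578 on average (-0.0650 to -0.0447), the correlation -0.287 to -0.182, and 81 to 247 genes were called in opposite directions against 10 to 50 in the same direction. Fewer arrays in each comparison lower these counts, so they do not say how many of the 552 opposite calls come from the shared arrays. Genes are not independent replicates, and an error common to all 3 T3 arrays would remain. The number moved back, 552, was 307 without euthyroid replicate 1, 328 without euthyroid replicate 3, 332 without T3 replicate 3 and 300 with median scaling.

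Among the genes raised by T3, the largest falls with the siRNA were those of Acot3 (1.96 with T3, then -2.59 ± 0.44), Unc79 (1.97, then -2.17 ± 0.33), the testosterone hydroxylase Cyp2b9 (2.09, then -2.03 ± 0.56), the glucuronosyltransferase Ugt1a5 (2.65, then -1.95 ± 0.34), Pck1 (1.54, then -1.94 ± 0.23) and Cyp17a1 (4.81, then -1.94 ± 0.46). The second change was no longer called for Cyp2b9 in 6 alternatives (up to 0.0953) and for Cyp17a1 without T3 replicate 2, T3 replicate 3, siRNA replicate 1 or siRNA replicate 3 (up to 0.0586). Among the genes lowered by T3, the largest rises with the siRNA were those of Gpnmb (at least 1.76-fold lower with T3, adjusted p = 0.049, then at least 25.4-fold higher), Acta2 (-2.07, then 4.42 ± 0.32), Col1a1 (-2.45, then 4.06 ± 0.20), the collagen Col8a1 (-1.43, then 3.12 ± 0.19), the membrane protein Emp1 (-1.06, then 2.98 ± 0.22) and the macrophage receptor Trem2 (-1.31, then 2.95 ± 0.27). Col1a1, Col8a1 and Trem2 were each detected on 1 of the 3 T3 arrays, and Unc79 on 1 of the 3 arrays of both other groups, so these changes start from or end at dim signals. With T3 and the siRNA together, 373 of the 813 genes raised by T3 were still past the threshold above euthyroid liver, 429 did not differ past it and 11 were past it in the opposite direction. Of the 1106 genes lowered by T3, 518 were still past the threshold under euthyroid liver, 537 did not differ past it and 51 were past it above. These genes were picked for their change with T3, so some of them would miss the threshold in another comparison without any effect of the siRNA. Many genes changed with the siRNA without a call for T3: 901 of the 1226 higher and 523 of the 809 lower, although no test compared them with the others.

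**Figure D3:**
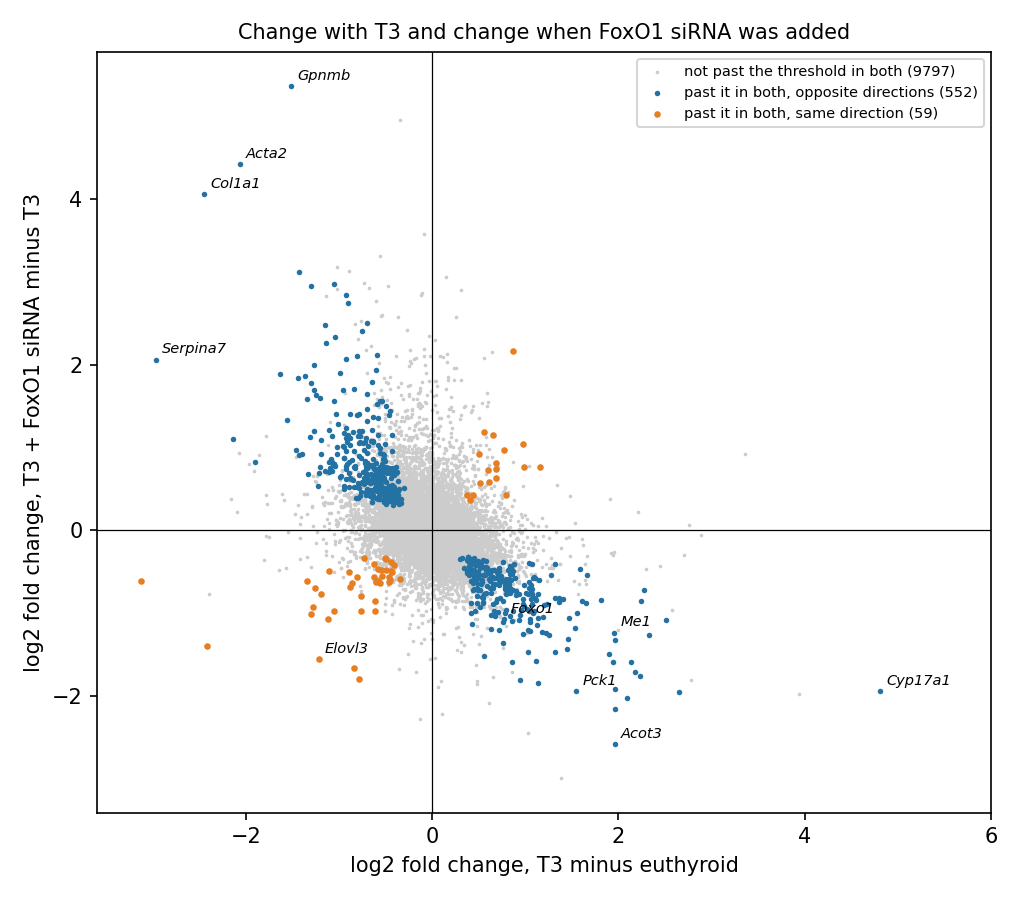
Log2 fold change of each of the 10408 genes with T3 (horizontal axis) against its log2 fold change when FoxO1 siRNA was added (vertical axis). The 552 genes past the threshold in both comparisons and in opposite directions are blue, and the 59 past it in both and in the same direction are orange.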

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

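The tests on the share of hepatocytes, on the injection, on a general fall of hepatocyte transcripts, on female mice, on cross-hybridization and with the T3 arrays divided between the comparisons were chosen after the results were seen. Leaving out each array in turn, the simulation for the shared arrays and the splits were chosen before. Of the arrays left out, siRNA replicate 3 is given below since it lay farthest from the others in these data.

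Probes without a gene name stand outside the comparisons by gene, and some of them changed. Of 2827 such probes 514 passed the threshold with T3 against euthyroid (226 higher and 288 lower), 249 with the siRNA against T3 (131 and 118) and 671 with the siRNA against euthyroid (285 and 386). No explanation was tested for them.

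With T3 and FoxO1 siRNA, 15 of 20 cell cycle genes, 6 of 10 macrophage markers, 7 of 11 stellate cell and fibroblast markers (2 lower) and 9 of 21 acute phase genes (1 lower) were higher than with T3 alone; with an estimated correlation these lists had an adjusted p = 0.251 to 0.264, and the acute phase list lost its call with median scaling (0.0877). A lower share of hepatocytes with every other cell type raised alike would raise macrophage and endothelial markers by about the same amount. These 2 lists differed. The comparison cannot decide on a lower share of hepatocytes with unequal changes of the other cells. The marker medians were 1.05 for stellate cells, 0.37 for cholangiocytes, 0.03 for lymphocytes and -0.12 for hepatocytes. The median of the macrophage markers exceeded that of the endothelial markers by 0.72 (log2, two-sided permutation p = 0.0033). The genes of both lists were shuffled and not the arrays, so that p-value does not measure the spread between samples. The rise of the cell cycle genes did not rest on the siRNA array farthest from the others: without siRNA replicate 3 the median rise of the cell cycle list was 1.28, against 1.46 with all arrays. The injection and the fall of Foxo1 cannot be told apart, since the labels name no group injected without FoxO1 siRNA and do not say whether the other mice had a control injection. Against euthyroid liver the cell cycle median was 1.55, while Foxo1 differed by -0.30 on its brighter probe and -0.69 on its dimmer one. A response of the liver to the injection and one to the fall of Foxo1 are both candidate explanations, as is a change in the macrophages and stellate cells themselves. A lower share of hepatocytes with unequal changes of the other cell types stays open as well.

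Of the 813 genes raised by T3, 245 were lower with the siRNA than with T3 alone and 18 rose further. With no T3 array in both comparisons, the covariance stayed below 0 in each of the 6 ways to divide the T3 arrays (highest -0.0447, SD 0.0084). The 6 ways reuse the same arrays, so this SD does not measure the uncertainty of the covariance. With all arrays the covariance was -0.0810 against a lowest simulated value of -0.0224. The simulated genes were independent of each other, and correlated genes would widen that range. The correlation of -0.385 was weaker than the -0.538 to -0.453 that the design sets without effects. The covariances thus argue against the shared arrays as the only source of the opposite changes, without a measure of chance. A fall of all hepatocyte transcripts to the same degree would lower the hepatocyte markers as far. Lipogenesis and cholesterol synthesis genes fell further, by -0.45 in the median (two-sided permutation p = 0.0157). Here too genes were shuffled and not arrays, so that p-value treats genes that move together as independent. It does not measure the spread between samples. Bright hepatocyte markers such as Ahsg, at 15.6 (log2) on the T3 arrays, lie near the top of the signal range. A fall may be compressed there, so this comparison cannot decide against a general fall. Without siRNA replicate 3 the lipogenesis median was -0.53, against -0.57 with all arrays. That FoxO1 may take part in the response of these genes to T3 stays a hypothesis. The injection stays open here too, as does a general fall of hepatocyte transcripts. The part of the opposite calls that comes from the shared arrays is not known.

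Of 10 female-biased genes 7 were higher with T3 and 1 lower; of 14 male-biased genes 6 were lower, 1 higher and 7 not past the threshold. With an estimated correlation the lists had an adjusted p = 0.251 and 0.515, and the male-biased list lost its call without T3 replicate 2 (0.143) and with array weights (0.0501). Female mice among the T3 arrays were argued against by the Y-linked Eif2s3y, whose lowest difference on a T3 array from the euthyroid mean was -0.0462. The 7 genes that rose come from 4 gene families, so close copies of 1 gene would not cover them all. Whether a probe reads a close copy within its own family was not tested. A change of the sex-biased programme of the liver with T3 may be the source, as a hypothesis found on these same data, and no sample tests its route.

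In each comparison by gene the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of the 10, gave 1919 genes for T3 against euthyroid, 2035 for the siRNA against T3 and 2785 for the siRNA against euthyroid. The highest of the other splits gave 0 in limma in each (463, 623 and 506 genes at an unadjusted p under 0.05, against 3640, 3647 and 4124 for the real splits). Every other split mixes arrays of both groups, so a difference between the groups widens the spread within the split. The 0 is thus in part built in and does not measure the noise.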

How the results depend on the processing

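The alternatives were all planned before the data were examined. The replicate numbers do not pair the arrays across groups: the correlations of arrays with the same number ranged from -0.056 to 0.029 and only 1 of 9 pairings matched its own number best, and with the replicate as a block the counts were 1525, 1663 and 2376 with 431 moved back. Median scaling moved the median of all genes to -0.10, 0.17 and 0.09 in the 3 comparisons (from -0.05, 0.01 and -0.02); the medians of the lists that passed keep their sign relative to it. It gave 916 genes for T3 against euthyroid (890 of them among the 1919), 1778 for the siRNA against euthyroid and 300 moved back (239 among the 552), with 88.7% and 73.6% of the genes higher for the siRNA against T3 and against euthyroid. A threshold of 1.5-fold gave 1072, 1281, 1624 and 274 moved back by its own construction. The covariance was -0.0479 with normexp, -0.0411 with the authors' values and -0.0543 without a filter, where fold changes are compressed or dim probes added. With an estimated correlation 0 lists passed. Hadh reversed to -0.58 against euthyroid with detection on all 9 arrays, where another probe stands for the gene, and Atp5a1 to -0.0213 with T3 with the mean of its probes. Leaving out 1 array gave 906 to 2041 genes for T3 against euthyroid, 1148 to 1791 for the siRNA against T3, 1698 to 2949 for the siRNA against euthyroid, 307 to 470 moved back, 34 to 43 lists, a covariance of -0.100 to -0.0749 and a Foxo1 change of -1.23 to -0.95. Fewer arrays lower the power, and the cause of the rest was not tested. Of the named genes' values under the processing alternatives 3546 were the same, 166 weaker, 110 stronger and 2 reversed; leaving out 1 array gave 2875, 265, 37 and 0. Of 38 counts of at least 4 genes in a list 20 fell more than 1.5-fold when 1 array was left out. For the lists the processing alternatives gave 933, 19, 35 and 0, and leaving out 1 array 765, 22, 23 and 0. A block by slide was not run, since no slide is given. Signal over background limits the folds of dim probes.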

Other observations

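The gene families described here were defined from the symbols' first letters after the data were seen (121 families of at least 10 tested genes, 363 tests). A family takes in every tested gene whose symbol starts with its letters, so the functional name given may not hold for each member. Each family keeps its direction under every scaling tried, and with an estimated correlation each has an adjusted p = 0.746. With T3, 6 of 15 glucuronosyltransferases (Ugt) rose (median 0.36, camera adjusted p = 0.00415), as did, among subunits of respiratory complexes, 4 of 19 Cox genes (median 0.23, adjusted p = 0.0186) and 3 of 10 Ndufb genes (median 0.31, adjusted p = 0.0186). Of 10 developmental transcription factors of the Sox family 5 fell (median -0.54, adjusted p = 0.0186). When the siRNA was added, 18 of 58 cytochrome P450 genes (Cyp) were lower and 2 higher (median -0.41, adjusted p = 0.00025), 8 of 15 Ugt genes were lower (median -0.46, adjusted p = 0.00415) and 7 of 13 carboxylesterases (Ces) were lower (median -0.47, adjusted p = 0.00415). Of the ribosomal protein genes 8 of 26 Rps (median 0.26, adjusted p = 0.00415) and 10 of 31 Rpl (median 0.21, adjusted p = 0.00534) rose, as did 7 of 15 nucleoporins (Nup; median 0.45, adjusted p = 0.00961), 10 of 24 collagens (Col; median 0.30, adjusted p = 0.0118) and 6 of 11 matrix metalloproteinases (Mmp; median 0.70, adjusted p = 0.0157). Relative to the median of all genes, the Rps shift was 0.25 and the Rpl shift 0.20, and they were 0.14 and 0.09 with median scaling. Over the scalings the shift went down to 0.28 for Nup (from 0.44), 0.16 for Col (from 0.29), 0.37 for Mmp (from 0.69), and, in the other comparisons, -0.27 for Sox (from -0.48) and 0.20 for Kif (from 0.41). Against euthyroid liver 7 of 17 kinesins (Kif) were higher and 2 lower (median 0.39, adjusted p = 0.0229), and 26 of 58 Cyp genes were lower and 8 higher (median -0.36, adjusted p = 0.0302).

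Other lists moved in few of their members or in both directions. Camera compares a list with all genes, and for some lists that did not pass its direction differs in sign from the median or mean. These are the clock, acute phase, xenobiotic and hepatocyte lists with T3 (medians and means below 0, camera up), and the xenobiotic and endothelial lists (means above 0) and the male-biased list (median above 0) with the siRNA against T3, where camera points down. The same holds against euthyroid for the FoxO targets and for the autophagy, cholangiocyte, lymphocyte and erythroid lists. In xenobiotic metabolism 3 of 21 genes rose (1 without euthyroid replicate 1) and 3 fell with T3 (4 and 4 adjusted over the list alone; median -0.09, camera adjusted p = 0.874), with the glutathione transferase Gstt1 at 1.66 ± 0.12 and the cytochromes Cyp1a2 at -1.57 ± 0.21 and Cyp2c29 at -1.30 ± 0.25. With the siRNA 3 rose and 4 fell (3 and 4 adjusted over the list alone; median -0.23, camera adjusted p = 0.195, past the threshold in 2 alternatives), with the glutathione transferases Gsta1 at 3.18 ± 0.43 (5.86 on both of its other probes) and Gsta2 at 3.13 ± 0.45 and the carboxylesterase Ces2a at -1.42 ± 0.24 (detected on 2 of 3 siRNA arrays). The falls were 2 without T3 replicate 2, T3 replicate 3, siRNA replicate 1 or siRNA replicate 3. In amino acid catabolism and the urea cycle 5 of 14 rose and 3 fell with T3 (6 and 4 adjusted over the list alone; median 0.25, camera adjusted p = 0.246), with Oat, of ornithine breakdown, at -1.75 ± 0.29 and Hpd at -0.77 ± 0.14. Only 1 rose without euthyroid replicate 2, and 2 without euthyroid replicate 1, euthyroid replicate 3 or T3 replicate 2. In gluconeogenesis 2 of 11, Pck1 and Mdh1, rose with T3 and 1, Gpt, fell, the last not called when any 1 of 4 arrays was left out (2 and 1 adjusted over the list alone; median 0.01, camera adjusted p = 0.545). Of 18 autophagy and lysosome genes 2 rose and 1, Atg7 (-0.62 ± 0.11), fell with T3 (2 and 1 adjusted over the list alone; camera adjusted p = 0.296). None rose without euthyroid replicate 1, euthyroid replicate 3 or T3 replicate 1. With the siRNA 3 rose, 1 without T3 replicate 3, siRNA replicate 1 or siRNA replicate 3, and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.298). Of 13 circadian clock genes 2 fell with the siRNA, Cry2 and the period gene Per1 (-0.84 ± 0.17), and none rose; only 1 fell without T3 replicate 2, T3 replicate 3 or siRNA replicate 3 (2 lower adjusted over the list alone; camera adjusted p = 0.204). None of 9 immediate early genes passed with the siRNA (0 adjusted over the list alone; camera adjusted p = 0.874).

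No cell cycle gene passed with T3 alone (0 of 20, also adjusted over the list alone; median 0.25, camera adjusted p = 0.0757, past the threshold in 6 alternatives). In the acute phase response 1 of 21, Itih3 (-0.71 ± 0.11), fell with T3 (1 adjusted over the list alone; camera adjusted p = 0.874), and in the interferon response 1 of 19, Mx2, fell with the siRNA, though not without T3 replicate 3 or siRNA replicate 3 (1 adjusted over the list alone; camera adjusted p = 0.56). Of 5 erythroid markers 2 fell with T3 (2 adjusted over the list alone), the haem synthesis gene Alas2 (-1.42 ± 0.17) and the anion exchanger Slc4a1 (-1.02 ± 0.22), and 2 rose with the siRNA (2 adjusted over the list alone), Slc4a1 (1.28 ± 0.22) and Hbb-b2, with camera adjusted p-values of 0.0562 and 0.0555, past the threshold in 7 and 9 alternatives. Only 1 fell without euthyroid replicate 3, and only 1 rose when any 1 of 7 arrays was left out. Of 6 neutrophil and monocyte markers 2 rose with the siRNA, Lyz1 (0.79 ± 0.18) and Il1b (2 adjusted over the list alone; median 0.52, camera adjusted p = 0.0684, past the threshold in 2 alternatives), and only 1 when any 1 of 4 arrays was left out. Of 9 endothelial markers 1, Stab1 (-0.49 ± 0.10), fell with T3 (1 adjusted over the list alone; camera adjusted p = 0.283). Of 4 cholangiocyte markers 2 rose with the siRNA, Sox9 (0.86 ± 0.13) and Krt7 (2 adjusted over the list alone; camera adjusted p = 0.382), and only 1 when any 1 of 7 arrays was left out. Of 6 lymphocyte markers 1, Ly6d (2.84 ± 0.60; detected on 1 of 3 T3 arrays), rose with the siRNA (1 adjusted over the list alone; camera adjusted p = 0.894). The 1 measured adipocyte marker, Lep, was not detected on the T3 arrays and was at least 1.13-fold higher with the siRNA, a call lost in most alternatives (1 adjusted over the list alone; camera adjusted p = 0.294).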
